A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

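Gene expression was measured with the Affymetrix yeast array in total RNA labelled with biotin. Wild type SEY6210 and a pmt1 pmt2 mutant of the same background each gave 2 arrays, and each array came from a separate biological sample according to the design text. Which part of PMT1 and PMT2 was altered in the mutant is not given in the sources used here. The labels state no batch and do not pair the arrays, although arrays of both groups carry the numbers 1 and 2.

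The deposited values are probe set signals in linear units (intensity) with 1 decimal, from 0 to 12590.3, for 9335 probe sets. The submitters' processing notes name GCRMA, without a version or settings, and the scaling between arrays is not stated. The values include zeros and many below 1 and share no common distribution over the arrays, which GCRMA output would not usually show, so which summary was deposited is uncertain and the signals are used as they stand. The array medians differed (54.4 to 66.1), and 5 to 11 probe sets per array were at 0. The values were taken to log2 with zeros set to 0.1, a value chosen after seeing the data, and no further normalization was applied. Of the probe sets, 6504 named 1 gene, 328 named several genes and 2503 carried no gene name, 60 of the latter being array controls. Where several probe sets named the same gene (315 genes), the probe set with the highest mean was used. That left 5656 genes, all of which matched a locus tag of the R64 assembly, which served only for names and for which genes neighbour each other. No filter on low signal was applied. Background was taken as the highest signal (26.2) of 19 control probe sets for bacterial and mouse transcripts, and 602 genes (10.6%) lay at or below it on all arrays. Where the lower group's mean lay below this level, the fold was computed against it and is given as a lower bound. The number of arrays limits the precision.

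Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the 5656 genes), and genes at adjusted p under 0.05 were counted as changed. A 2 against 2 design leaves 2 residual degrees of freedom before moderation, and an exact permutation test of a single gene could not go below p = 0.333. The control probe sets set the arrays numbered 1 apart from those numbered 2, so every comparison was also fitted with the array number as a replicate block, and fold changes are given within each number. Gene lists were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation, and with fry, with Benjamini-Hochberg over the 33 lists; the 16 nuclear chromosomes were tested as a family of their own. Camera compares a list with all other genes, whereas fry tests whether the members move on balance to 1 side or, in its mixed form, to either side. At an estimated correlation camera tests each list on the 2 residual degrees of freedom alone, which leaves little room for any list to pass.

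The comparison, the tests, the 33 lists and the rule for naming genes were chosen before the data were examined. The rule took PMT1 and PMT2, then up to 15 genes with the largest rise and up to 15 with the largest fall among changed genes whose arrays did not overlap between groups and whose higher group mean was at least 6 on the log2 scale, then up to 4 members of each described list with the smallest p. Genes named beyond this rule were chosen after their values were seen, and the text says so. The lists were cell wall integrity targets, unfolded protein response targets, ER-associated degradation, protein O-mannosylation, N-glycosylation, cell wall glucan and chitin enzymes, structural cell wall mannoproteins, cell wall and osmosensor signalling, osmotic stress targets, pheromone response, filamentous growth targets, a-cell genes, alpha-cell genes, meiosis and sporulation, environmental stress (induced), heat shock chaperones, ribosomal proteins, ribosome biogenesis, amino acid biosynthesis, sulfur and methionine, phosphate starvation, iron regulon, calcineurin targets, glycolysis and fermentation, hexose transport, respiration, ergosterol synthesis, phospholipid synthesis, daughter cell separation, histones, cyclins, strain marker loci, and seripauperin and subtelomeric families. Some genes belong to several lists.

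Alternatives tried were quantile normalization, centring each array on its median, a minimum mean log2 value of 4 or 6, raising log2 values below 4 to 4, a mean-variance trend, robust spread estimation, the mean of all probe sets of a gene, every probe set on the array, the replicate block, and leaving out each array in turn. The block combined with the minimum of 6 or with the trend was added after seeing the data. Fits without 1 array had no block and left the groups unequal in array number. Without pmt1 pmt2 array 2 or array 1 the median log2 change of all genes was −0.14 or 0.24. The fits were tested on simulated data with 200 of 5656 genes changed in each of 20 runs. Each simulated gene carried the array-number effect fitted to the real data, and its spread was drawn from the block fit. The higher recovery with the block was thus built in and does not show that the arrays are paired. Without the block the test recovered 0.1% of genes at a true log2 change of 1, 3% at 2, 61.6% at 3 and 88.4% at 4, and 0.0653% of its calls were false. With the block it recovered 21.6%, 94.1%, 99.6% and 99.9%, and 9.79% of its calls were false. Among 660 simulated lists with no effect, camera gave an unadjusted p under 0.05 in 2.58%. Beyond the array-number effect, the simulated noise was drawn for each gene separately. This rate therefore does not cover lists whose members vary together in other ways. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.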

Results

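Transcript levels of exponentially growing Saccharomyces cerevisiae were compared between wild type SEY6210 (n = 2 arrays) and pmt1 pmt2 cells of the same background (n = 2 arrays). PMT1 and PMT2 encode protein O-mannosyltransferases of the endoplasmic reticulum, which attach mannose to serine and threonine residues of secretory and cell wall proteins. Median signals were 59.8 and 55.3 on the wild type arrays and 54.4 and 66.1 on the pmt1 pmt2 arrays. The share of the 5656 tested genes above background was 82.6% and 81.6% in wild type and 81.6% and 86.0% in pmt1 pmt2. Levels below are deposited signals as mean ± SD of 2 arrays per group, and fold changes are ratios of geometric means.

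The comparison asks which transcripts differ in cells mutated for both genes. The mutated genes themselves were lower. PMT1 (YDL095W) fell from 993 ± 261 in wild type to 108 ± 5.37 in pmt1 pmt2, 9.08-fold (log2 change −3.18 ± 0.37 (SE), limma adjusted p = 0.0382, and 0.00202 with the replicate block). PMT2 (YAL023C) fell from 2708 ± 88.6 to 13.7 ± 2.55, under the background level of 26.2. The fall was at least 103-fold (log2 change −7.64 ± 0.35 (SE), limma adjusted p = 0.00309, and 8.43e-05 with the block). Within the arrays numbered 1 and 2 the log2 changes were −3.40 and −2.96 for PMT1 and −7.80 and −7.48 for PMT2. Leaving out pmt1 pmt2 array 1 or array 2 kept the PMT1 log2 fold change at −3.23 or −3.13 but took its limma adjusted p to 0.187 or 0.242. Without pmt1 pmt2 array 1 the PMT2 log2 fold change was −7.45 with adjusted p = 0.0591. PMT1 also missed limma's threshold after quantile normalization (adjusted p = 0.0753), after centring (0.0593) and with low values raised to a log2 of 4 (0.285), and both genes missed it over every probe set on the array (0.307 and 0.120).

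Genes of the cell wall and stress lists were among the largest rises. PIR3 (YKL163W), an O-mannosylated protein linked to wall glucan, rose 25.1-fold from 48.3 ± 16.8 to 1283 ± 727 (log2 change 4.65 ± 0.53 (SE), 4.04 without pmt1 pmt2 array 2 and 5.26 without array 1). The multistress gene DDR2 (YOL052C-A) rose 21.1-fold, from 232 ± 53.9 to 4839 ± 464 (log2 change 4.40 ± 0.37 (SE)). HSP12 (YFL014W), which encodes a small heat shock protein of membranes, rose 13.6-fold from 136 ± 49.99 to 1789.8 ± 224. The GPI-anchored aspartyl protease gene YPS3 (YLR121C) rose 13.1-fold from 144 ± 10.3 to 1973 ± 841. The wall protein gene NCW2 (YLR194C) rose 9.28-fold from 214.5 ± 25.3 to 1989.6 ± 236. ARG1 (YOL058W), for argininosuccinate synthetase, rose 11.03-fold from 133 ± 17.96 to 1465 ± 42.4. RTC3 (YHR087W) rose 14.9-fold and MNC1 (YBR056W-A) 12.6-fold. NCA3 (YJL116C), of the SUN family, rose 8.296-fold, and NFG1 (YLR042C), a negative regulator of filamentous growth, 7.06-fold. The transaldolase homologue NQM1 (YGR043C) rose at least 8.07-fold to 212 ± 20.2. The methyltransferase gene CRG1 (YHR209W) rose at least 2.75-fold to 73.2 ± 17.7. AGX1 (YFL030W), for alanine:glyoxylate aminotransferase, rose at least 8.88-fold to 234 ± 38.5. All 3 had wild type means under background. Beyond PMT1 and PMT2, the largest falls among changed genes with a higher group mean of at least 6 (log2) were in YAR068W and FIG1. YAR068W fell from 219 ± 19.2 to 4.25 ± 1.77 (at least 8.36-fold, log2 change −5.75 ± 0.42 (SE)). FIG1 (YBR040W), a membrane protein for calcium influx during mating, fell from 265 ± 52.3 to 15.7 ± 6.22 (at least 10-fold, log2 change −4.12 ± 0.43 (SE)). YAR068W has a near-identical copy elsewhere in the genome, so the source of its signal is uncertain. The limma adjusted p of these genes lay between 0.0242 (YAR068W) and 0.0449 (NCA3 and NFG1). With the block it lay between 5.61e-04 (YAR068W) and 0.00280 (CRG1 and NFG1).

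**Figure D1:**
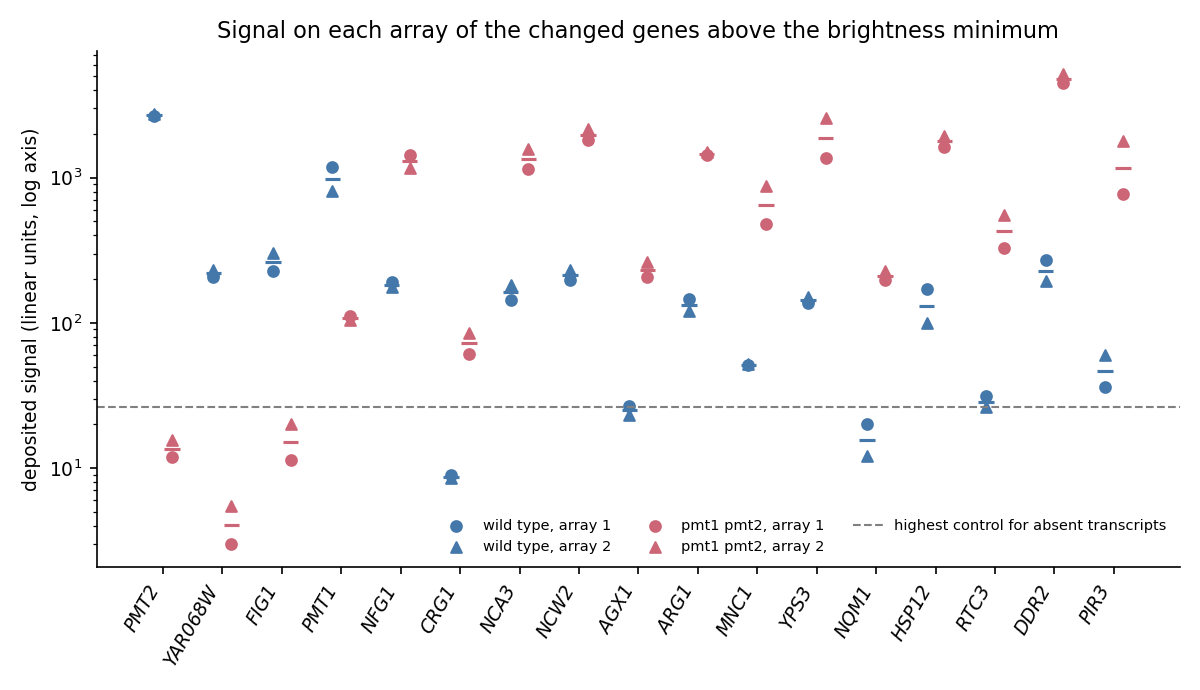
Deposited signal (linear units on a log axis) on each of the 4 arrays for the 17 changed genes whose higher group mean was at least 6 on the log2 scale, with circles for arrays numbered 1, triangles for arrays numbered 2 and bars for the geometric mean of each group. The dashed line marks the background level of 26.2, and in every gene shown both pmt1 pmt2 arrays lie to the same side of both wild type arrays.

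In all, 22 of 5656 genes changed at limma's adjusted p under 0.05, of which 16 were higher and 6 lower in pmt1 pmt2. All 22 had non-overlapping groups, which passing limma's test makes likely, so this adds no separate support. With exchangeable arrays chance gives such groups in 33.3% of genes at 2 against 2 arrays. At unadjusted p under 0.05 the count was 406. The other 5 changed genes were dim, with a higher group mean under 6 on the log2 scale. URA3 (YEL021W) rose to 54.5 ± 3.32 from 2.55 ± 0.919 (at least 2.08-fold), and PRM2 (YIL037C) fell from 23.9 ± 5.303 to 2.10 ± 0.141, both under background. SPG4 (YMR107W), YPT53 (YNL093W) and BI2 (Q0110), chosen for naming after their values were seen, had means of at most 21.05 in either group, so no fold is given for PRM2 or for these genes. Control probe sets set the arrays numbered 1 apart from those numbered 2. The ratio of the tail-end to the start-end actin control probe set was 2.99 and 3.15 on the arrays numbered 1 of wild type and pmt1 pmt2, against 1.38 and 1.32 on those numbered 2. With the array number as a replicate block, 131 genes were higher and 40 lower, the 22 among them. On data simulated with an array-number effect, 9.79% of the calls of this fit were false, above the nominal 0.05, although the noise was drawn from the same fit. Genes with an adjusted p just under 0.05 with the block are therefore uncertain. Of 3763 genes with a higher group mean of at least 6 on the log2 scale, 127 were at least 2-fold higher and 62 at least 2-fold lower within both numbers, and 1 was 2-fold apart in opposite directions. Across these genes, which are not independent replicates, the log2 changes of the numbers correlated at r = 0.83. The count moved when 1 array was left out, although all 22 genes kept their direction. It was 0 without pmt1 pmt2 array 1 (612 at limma's unadjusted p under 0.05), 1 without pmt1 pmt2 array 2, 62 without wild type array 1 and 44 without wild type array 2. It was 2 after quantile normalization, 14 after centring, 38 with a minimum mean log2 value of 6, 1 with low values raised to 4, and 0 over every probe set on the array (510 at limma's unadjusted p under 0.05).

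**Figure D2:**
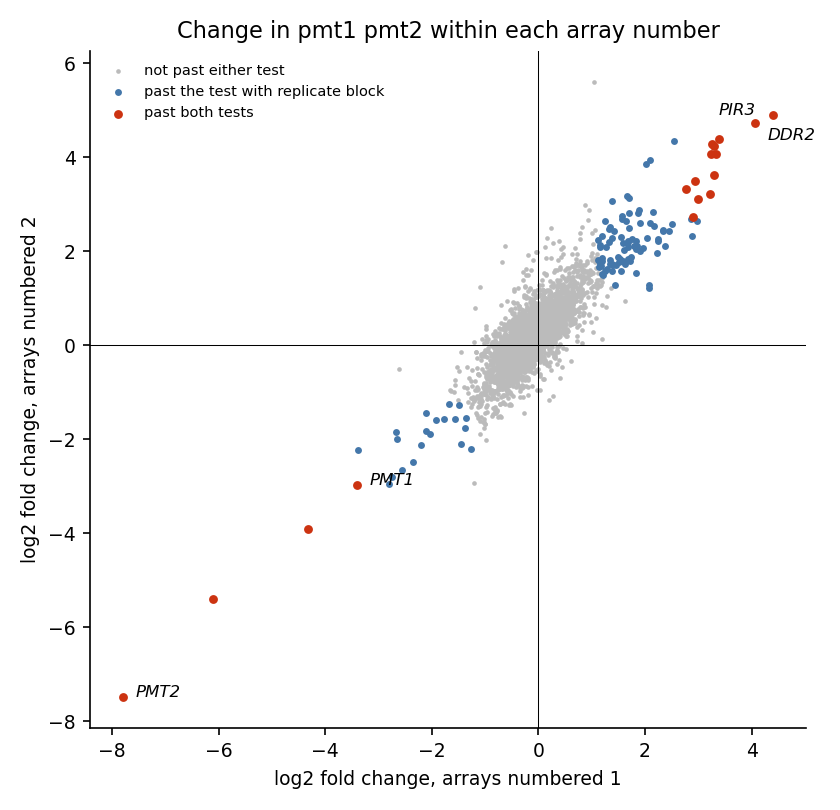
Log2 fold change of pmt1 pmt2 over wild type within the arrays numbered 1 (horizontal axis) and within those numbered 2 (vertical axis) for 3763 genes with a higher group mean of at least 6 on the log2 scale. The 17 genes past limma's test with and without the replicate block are red and the 105 past it only with the block are blue, and PMT1 and PMT2 lie far below 0 on both axes.

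Targets of the cell wall integrity pathway were higher as a group. All 31 had a log2 change above 0 within both array numbers, with a median of 1.47 (1.18 and 1.72 within the numbers). For comparison, the median log2 change of all genes was 0.027 (−0.15 and 0.21 within the numbers). NCW2, PIR3, YPS3 and CRG1 rose and the other 27 did not pass limma's test, while 17 were higher and 0 lower adjusted over the list alone, and 17 passed with the block. Camera gave the list an adjusted p = 8.87e-23 with the preset correlation, and adjusted p = 0.649 with an estimated correlation. Calcineurin targets share NCW2, GSC2, PUN1, CRH1 and YPS1 with that list, so the lists are not independent. Their median log2 change was 0.90 (0.73 and 1.15 within the numbers). Of the 19 calcineurin targets tested, NCW2 rose and 18 did not pass limma's test, with 4 higher and 0 lower adjusted over the list alone. For them camera gave adjusted p = 1.87e-08, against adjusted p = 0.649 with an estimated correlation. GSC2 (YGR032W), also called FKS2, encodes a subunit of glucan synthase. It measured 239 ± 11.3 in wild type and 1300.2 ± 60.1 in pmt1 pmt2, a 5.45-fold difference (limma adjusted p = 0.0746, and 0.005196 with the block). PUN1 (YLR414C), a plasma membrane protein, measured 453 ± 90.6 and 1932 ± 369 (adjusted p = 0.142 by limma, 0.0159 with the block). The glycosidase gene CRH1 (YGR189C), which links chitin to glucan, measured 954 ± 153 and 2606 ± 30.8 (limma adjusted p = 0.272, 0.0387 with the block). GSC2 and CRH1 also belong to the 39 glucan and chitin enzymes, whose median log2 change was 0.31 (0.19 and 0.48 within the numbers). None of the 39 passed limma's test (0 called, 5 higher at unadjusted p under 0.05, 1 higher and 0 lower adjusted over the list alone, 2 with the block). Camera gave the set an adjusted p = 0.01302 and adjusted p = 0.791 with an estimated correlation. The 37 genes of cell wall and osmosensor signalling, SLT2, KDX1, PTP2 and RLM1 of which are also integrity targets, had a median of 0.27 (0.094 and 0.35 within the numbers). Of these, 0 passed limma's test (4 higher and 1 lower at unadjusted p under 0.05, 0 adjusted over the list alone). Camera gave them an adjusted p = 0.02098, and adjusted p = 0.791 with an estimated correlation. SLT2 (YHR030C), the MAP kinase of the integrity pathway, measured 181 ± 8.27 and 538 ± 196 (limma adjusted p = 0.352, 0.0442 with the block). Its paralogue KDX1 (YKL161C) measured 10.2 ± 4.31 and 53.5 ± 39.95 (at least 1.73-fold higher, limma adjusted p = 0.427, 0.0128 with the block). By deposited values, with wild type under background, the KDX1 log2 change was 1.36 without pmt1 pmt2 array 2 and 3.06 without array 1. WSC4 (YHL028W), of the sensor family of the pathway, was lower at 133 ± 17.3 and 54.4 ± 11.7 (limma adjusted p = 0.417, 0.0656 with the block), and 11 of the 37 had a log2 change below 0. Structural mannoproteins of the wall went both ways. Of the 32 tested, PIR3 rose and 31 did not pass limma's test, with 3 higher and 3 lower adjusted over the list alone, and also 3 and 3 with the block. The median was 0.22, with camera adjusted p = 0.766. The cell wall glucan and chitin enzymes list lost its call without wild type array 1 (camera adjusted p = 0.173) or pmt1 pmt2 array 2 (0.0752). The cell wall and osmosensor signalling list lost it without the same arrays (0.173 and 0.166). These shifts depended on the arrays: without pmt1 pmt2 array 2 or array 1 the median was 0.14 or 0.74 for the enzymes, 0.028 or 0.50 for signalling and 0.0032 or 0.52 for the structural mannoproteins. The median of all genes moved too in these fits, to −0.14 or 0.24.

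Targets of the unfolded protein response were moderately higher as a group, with a median log2 change of 0.65 (0.52 and 0.78 within the numbers) and 19 of 24 above 0 in both. None of the 24 passed limma's test alone (0 called, 7 higher at unadjusted p under 0.05, 0 adjusted over the list alone). Camera gave the list an adjusted p = 1.53e-07, and adjusted p = 0.649 with an estimated correlation. ULI1 (YFR026C), which passed with the block, measured 19.2 ± 4.38 in wild type and 62.2 ± 5.303 in pmt1 pmt2 (at least 2.37-fold higher, limma adjusted p = 0.203, 0.0274 with the block). ERO1 (YML130C), the thiol oxidase of the endoplasmic reticulum, measured 79.9 ± 22.1 and 222 ± 42.1 (limma adjusted p = 0.343, 0.0575 with the block). SIL1 (YOL031C), an exchange factor for Kar2, measured 131 ± 14.8 and 306 ± 17.5, and MPD1 (YOR288C), a protein disulfide isomerase, 71.3 ± 13.01 and 174 ± 41.6. The 19 genes of ER-associated degradation had a median of 0.28 (0.083 and 0.50 within the numbers) with camera adjusted p = 0.115. Among these, 0 passed limma's test (1 higher at unadjusted p under 0.05, 0 adjusted over the list alone). Protein O-mannosylation genes other than the mutated pair had a median of 0.13 (0.020 and 0.28 within the numbers), with camera adjusted p = 0.413. Here 0 of 15 passed limma's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone). Among them, PMT3 (YOR321W) measured 197 ± 3.32 and 297 ± 46.7, MNN1 (YER001W) 248 ± 1.91 and 426.5 ± 70.7, and KTR1 (YOR099W) 830.2 ± 313 and 1346 ± 183. KTR3 (YBR205W) measured 638 ± 96.03 and 514 ± 12.2 (limma adjusted p = 0.994), while another KTR3 probe set, not used, measured 268 and 275. Of the 15, 6 had a log2 change below 0, and without pmt1 pmt2 array 2 or array 1 the median was 0.032 or 0.24. N-glycosylation genes had a median of 0.027 that turned to −0.011 after quantile normalization and −0.066 after centring. Camera gave adjusted p = 0.782, and 0 of 34 passed limma's test (1 higher at unadjusted p under 0.05, 1 higher and 0 lower adjusted over the list alone). That gene was OCH1 (YGL038C), a mannosyltransferase of the Golgi that starts outer chains, at 73.8 ± 9.83 and 335 ± 85.7 (limma adjusted p = 0.133, 0.00875 with the block).

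General stress genes were higher as a group, and heat shock chaperones did not pass the set test. The 38 induced genes of the environmental stress response had a median log2 change of 1.10 (0.67 and 1.45 within the numbers), and 34 were above 0 in both. DDR2 and HSP12 rose and 36 did not pass limma's test, with 12 higher and 0 lower adjusted over the list alone and 9 past the test with the block. Camera gave an adjusted p = 6.28e-17, and adjusted p = 0.649 with an estimated correlation. The repressor gene XBP1 (YIL101C) measured 17.1 ± 11.1 and 166 ± 31.1 (at least 6.30-fold higher, limma adjusted p = 0.0998, 0.00948 with the block). By deposited values, with wild type under background, its log2 change was 2.73 without wild type array 2 and 4.16 without array 1. The cytosolic catalase gene CTT1 (YGR088W) measured 11.3 ± 1.06 and 43.1 ± 3.89 (at least 1.64-fold higher, limma adjusted p = 0.142, 0.0145 with the block). Osmotic stress targets, which share HSP12, CTT1, HOR7 and RTN2 with that list, had a median of 0.86 (0.63 and 1.39 within the numbers). HSP12 and NQM1 rose and the other 17 of the 19 tested did not pass limma's test, with 6 higher and 0 lower adjusted over the list alone. For them camera gave adjusted p = 1.14e-10, against adjusted p = 0.649 with an estimated correlation. GPD1 (YDL022W), for the glycerol-phosphate dehydrogenase of glycerol synthesis, measured 652 ± 115 and 2526 ± 808 (limma adjusted p = 0.198, 0.0277 with the block). Heat shock chaperones had a median of −0.052, a mean of 0.069 and a downward camera test with adjusted p = 0.858, so median and mean differed in sign. In this list 0 of 25 passed limma's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone). Respiration genes were higher by a median of 0.49 (0.22 and 0.77 within the numbers). Without pmt1 pmt2 array 2 or array 1 the median was 0.61 or 1.52 for the stress genes and 0.47 or 1.33 for the osmotic stress targets. It was 0.25 or 0.80 for the respiration genes, and −0.14 or 0.24 for all genes. For the respiration genes camera gave adjusted p = 8.96e-06, against adjusted p = 0.6999 with an estimated correlation. None of the 53 passed limma's test alone (0 called, 4 higher at unadjusted p under 0.05, 0 adjusted over the list alone). CIT2 (YCR005C), a peroxisomal citrate synthase, measured 391 ± 94.4 and 833 ± 184, and SDH4 (YDR178W), of succinate dehydrogenase, 710.3 ± 24.9 and 1354 ± 252. Glycolysis and fermentation genes had a median of −0.032 that turned to 0.023 after quantile normalization, a mean of 0.16 and an upward camera test with adjusted p = 0.627. Of them, 0 of 27 passed limma's test (2 higher at unadjusted p under 0.05, 0 adjusted over the list alone). Hexose transport genes went both ways around a median of −0.20 (camera adjusted p = 0.522). There, 0 of 18 passed limma's test (3 higher and 2 lower at unadjusted p under 0.05), with 2 higher and 1 lower adjusted over the list alone. The transporter gene HXT4 (YHR092C) measured 747 ± 332 in wild type and 142 ± 20.1 in pmt1 pmt2 (limma adjusted p = 0.162, 0.009204 with the block). HXT5 (YHR096C), under background in wild type, measured 19.1 ± 6.86 and 91.2 ± 33.6 (limma adjusted p = 0.182, 0.00746 with the block). HXT1 (YHR094C) measured 678 ± 178 and 2105 ± 326 (limma adjusted p = 0.252, 0.0397 with the block).

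**Figure D3:**
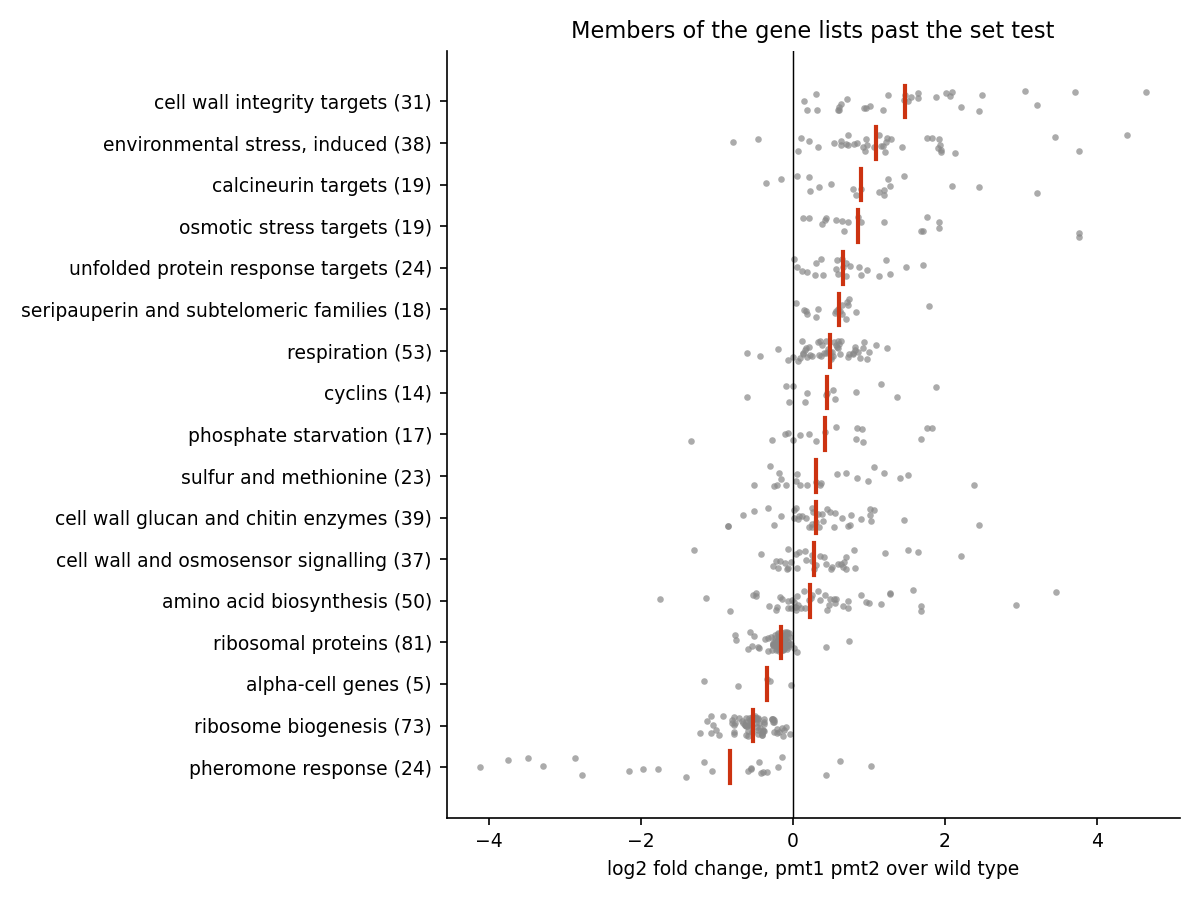
Log2 fold change of pmt1 pmt2 over wild type for each member (grey points) of the 17 lists at camera adjusted p under 0.05 with the preset correlation, with the number of tested members in brackets and a red bar at the median. Cell wall integrity targets have the highest median, 1.47, and pheromone response genes the lowest, −0.83.

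Mating genes were lower as a group. The 24 pheromone response genes had a median log2 change of −0.83 (−1.08 and −0.62 within the numbers), with 18 below 0 and 3 above 0 in both numbers. FIG1 and PRM2 fell and 22 did not pass limma's test, with 0 higher and 11 lower adjusted over the list alone and 9 lower with the block. Camera gave an adjusted p = 2.66e-12, and adjusted p = 0.649 with an estimated correlation. PRM1 (YNL279W), for membrane fusion at mating, measured 269.9 ± 62.9 in wild type and 39.4 ± 8.06 in pmt1 pmt2 (limma adjusted p = 0.0746, 0.00287 with the block). The wall adhesin gene FIG2 (YCR089W) measured 406 ± 136 and 55.0 ± 14.8 (limma adjusted p = 0.0836, 0.00273 with the block). AGA1 (YNR044W), the anchor subunit of agglutinin, measured 2486 ± 208 and 554 ± 20.8 (limma adjusted p = 0.0998, 0.00825 with the block). Alpha-cell genes had a median of −0.35 (−0.38 and −0.32 within the numbers). While 0 of 5 passed limma's test (1 lower at unadjusted p under 0.05, 0 adjusted over the list alone), camera gave an adjusted p = 0.0193, and adjusted p = 0.649 with an estimated correlation. Among them, the agglutinin gene SAG1 (YJR004C) measured 4803 ± 1011 and 2125 ± 335 and the pheromone gene MF(ALPHA)2 (YGL089C) 4162.5 ± 499 and 2521 ± 86.6. Only 3 of the 8 a-cell genes were above background on any array, and AXL1 (YPR122W), one of these and named after its values were seen, is made by haploid cells of either mating type. The list had a median of −0.075 (−0.48 and 0.16 within the numbers) with camera adjusted p = 0.276. From it, 0 passed limma's test (1 higher and 1 lower at unadjusted p under 0.05). The 1 lower adjusted over the list alone was MFA2 (YNL145W), a pheromone gene of a cells, at 111 ± 21.5 and 16.3 ± 5.94 (at least 4.20-fold lower, limma adjusted p = 0.0836, 0.00825 with the block). Filamentous growth targets went both ways around a median of 0.32 (camera adjusted p = 0.267). NFG1 rose and the other 16 did not pass limma's test, with 2 higher and 1 lower adjusted over the list alone. The adhesin gene FLO11 (YIR019C) measured 420.1 ± 75.3 and 88.3 ± 20.3 (limma adjusted p = 0.126, 0.0126 with the block). The wall protein gene SVS1 (YPL163C) measured 1001 ± 30.2 and 2945 ± 412 (limma adjusted p = 0.229, 0.0312 with the block). The mucin sensor gene MSB2 (YGR014W) measured 555 ± 22.8 and 1284 ± 158 (limma adjusted p = 0.424, 0.0606 with the block). Meiosis and sporulation genes had a median of 0.38 with 4 of 24 above background on any array, and camera adjusted p = 0.322. Of these 24, 0 passed limma's test (3 higher at unadjusted p under 0.05, 1 higher and 0 lower adjusted over the list alone). The alpha-cell genes list lost its call without wild type array 1 (camera adjusted p = 0.126), wild type array 2 (0.157) or pmt1 pmt2 array 2 (0.109), and with the block and a minimum mean log2 value of 6 together (0.0771), a setting chosen after seeing the data. Its median was −0.62 or −0.26 without pmt1 pmt2 array 2 or array 1. The filamentous growth median was 0.078 without wild type array 2 and 0.72 without pmt1 pmt2 array 1, and the meiosis median 0.12 without wild type array 1.

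Genes of ribosome assembly were lower by a small margin. All 73 ribosome biogenesis genes had a log2 change below 0, with a median of −0.52 (−0.48 and −0.53 within the numbers), and 68 were below 0 in both. None passed limma's test alone (0 called, 6 lower at unadjusted p under 0.05, 0 adjusted over the list alone). Camera gave an adjusted p = 5.59e-14, and adjusted p = 0.559 with an estimated correlation. KRR1 (YCL059C), of the small subunit processome, measured 142 ± 10.6 and 67.1 ± 4.81, NOP16 (YER002W) 168 ± 23.8 and 76.95 ± 17.6, and the RNA polymerase I subunit gene RPA43 (YOR340C) 191 ± 31.7 and 93.8 ± 4.596. The 81 ribosomal protein genes had a median of −0.16 (−0.18 and −0.16 within the numbers). Camera gave adjusted p = 0.00122, and adjusted p = 0.6999 with an estimated correlation. Of these 81, 0 passed limma's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone). Amino acid biosynthesis genes had a median of 0.22 (0.11 and 0.30 within the numbers). Of the 50 tested, ARG1 rose and 49 did not pass limma's test, with 4 higher and 0 lower adjusted over the list alone. For them camera gave adjusted p = 0.00841, against adjusted p = 0.791 with an estimated correlation. The arginine genes ARG4 (YHR018C), ARG3 (YJL088W) and ARG7 (YMR062C) passed with the block (limma adjusted p = 0.0211, 0.0176 and 0.02705), while CPA1 (YOR303W) and ARG8 (YOL140W), chosen after their values were seen, did not (0.0529 and 0.452). ARG4 measured 572 ± 85.1 and 1831 ± 181, ARG3 20.6 ± 16.6 and 130.0 ± 1.697, and ARG7 149.7 ± 6.93 and 451 ± 73.9. The wild type mean of ARG3 lay under background, so its rise was at least 4.96-fold. By deposited values the ARG3 log2 change was 2.00 without wild type array 2 and 3.87 without array 1. Sulfur and methionine genes had a median of 0.31 (0.25 and 0.50 within the numbers). Camera gave adjusted p = 0.01302, and adjusted p = 0.791 with an estimated correlation. Of these 23, 0 passed limma's test (3 higher at unadjusted p under 0.05, 1 higher and 0 lower adjusted over the list alone). STR3 (YGL184C), a cystathionine beta-lyase, measured 32.4 ± 1.56 and 181 ± 92.6 (limma adjusted p = 0.164, 0.0126 with the block). Phosphate starvation genes had a median of 0.42 (0.26 and 0.57 within the numbers). This list shares GPP2 (YER062C), entered in it as HOR2, with the osmotic stress targets and PHO89 (YBR296C) with the calcineurin targets. GPP2 measured 159 ± 71.0 and 530 ± 304 and was 1 of the 2 members higher at limma's unadjusted p under 0.05. Camera gave adjusted p = 0.01302, and adjusted p = 0.6999 with an estimated correlation. Of these 17, 0 passed limma's test (2 higher at unadjusted p under 0.05, 0 adjusted over the list alone). Iron regulon genes had a median of −0.13 (−0.37 and 0.12 within the numbers; camera adjusted p = 0.0884). Of these 29, 0 passed limma's test (2 lower at unadjusted p under 0.05, 0 adjusted over the list alone). Ergosterol synthesis genes had a median of −0.11 (camera adjusted p = 0.115). Of these 26, 0 passed limma's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone). Phospholipid synthesis genes had a median of −0.10, a mean of 0.053 and a downward camera test with adjusted p = 0.522. Of these 20, 0 passed limma's test (1 higher at unadjusted p under 0.05, 0 adjusted over the list alone). Without wild type array 1 the ribosomal proteins list (camera adjusted p = 0.119), the amino acid biosynthesis list (0.126), the sulfur and methionine list (0.181) and the phosphate starvation list (0.1497) lost their calls. Without pmt1 pmt2 array 2 the ribosomal proteins list and the sulfur and methionine list lost their calls. The sulfur and methionine median was then −0.075, below 0 but above the median of all genes in that fit, −0.14. The phosphate starvation list lost its call without pmt1 pmt2 array 1 (0.0837), with low values raised (0.0701), and with a minimum mean log2 value of 6 without the block (0.282) or with it (0.2795), where its median was 0.044. After quantile normalization the ribosomal proteins list lost its call (0.0505). Without pmt1 pmt2 array 2 or array 1 the median of the amino acid genes was 0.026 or 0.50, and without array 1 it was 0.82 for the sulfur and methionine genes and 0.68 for the phosphate genes. The ribosomal proteins median was −0.061 without pmt1 pmt2 array 2 and −0.25 without wild type array 2. The iron regulon list was past the test without pmt1 pmt2 array 2 (median −0.47, camera adjusted p = 0.00870).

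Cyclin genes were higher as a group by a median of 0.44 (0.22 and 0.56 within the numbers). For them camera gave adjusted p = 0.01302, against adjusted p = 0.663 with an estimated correlation. None of the 14 passed limma's test alone (0 called, 3 higher at unadjusted p under 0.05, 1 higher and 0 lower adjusted over the list alone). PCL1 (YNL289W) measured 45.05 ± 3.46 and 169 ± 46.8 (limma adjusted p = 0.177, 0.0159 with the block). PCL5 (YHR071W) measured 298 ± 15.98 and 769.9 ± 97.1 (limma adjusted p = 0.323, 0.0453 with the block). Both encode partners of the Pho85 kinase. Daughter cell separation genes had a median of 0.013 that turned to −0.024 after quantile normalization and −0.080 after centring, a mean of 0.040 and a downward camera test with adjusted p = 0.934. Of those 17 genes, 0 passed limma's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone). The 4 histone genes tested had a median of −0.052 (camera adjusted p = 0.824). Of these 4, 0 passed limma's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone). Of the 10 strain marker loci, URA3 rose and 9 did not pass limma's test, 1 was higher and 0 lower adjusted over the list alone. The median was 0.33, and camera gave an adjusted p = 0.0971. Seripauperin and subtelomeric family genes, whose near-identical copies make single members uncertain, had a median of 0.60 (0.29 and 0.87 within the numbers). For them camera gave adjusted p = 0.00122, against adjusted p = 0.6999 with an estimated correlation. Of these 18 genes 0 passed limma's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone). The cyclins list lost its call without wild type array 1 (camera adjusted p = 0.126), wild type array 2 (0.0578) or pmt1 pmt2 array 1 (0.0849), and its median was 0.16 without pmt1 pmt2 array 2. The strain marker loci list was past the test without wild type array 2 (median 0.79, camera adjusted p = 0.00907).

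Across the 33 lists, 13 were higher and 4 lower by camera with the preset correlation, and 17 were past the test with the replicate block. With an estimated correlation camera left 0 lists past the test (adjusted p from 0.559 to 0.976), and so did fry (0.195 to 0.966). Fry's mixed form, for change in either direction, left 13 (0.0114 to 0.904). The camera result at an estimated correlation rests on 2 residual degrees of freedom, so it does not show that correlation among members accounts for the shifts. Ribosome biogenesis lost its call although its estimated correlation was 0.012, near the preset 0.01. The other lists past the test, except the alpha-cell genes (−0.086), had higher estimates. These were 0.41 for cell wall integrity targets, 0.54 for environmental stress, 0.40 for osmotic stress, 0.29 for the unfolded protein response and 0.12 for pheromone response. Such estimates also rest on 2 residual degrees of freedom. Where members do vary together more than the preset allows, camera's p-values at the preset are too small. None of the 16 nuclear chromosomes was shifted as a whole (0 at camera adjusted p under 0.05, all at 0.972, with a lowest unadjusted p = 0.0857).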

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

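The test of URA3 against noise of a dim probe set was chosen only after the result was seen, whereas the tests of the pyrimidine pathway and of YAR068W were set before the values they measure were seen.

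The array's own control probe set for URA3, which the gene comparison leaves out, carried a difference between the groups, from a wild type level under background. It measured 24.0 ± 3.82 in wild type and 124.65 ± 30.2 in pmt1 pmt2 (at least 4.69-fold, log2 change 2.36 ± 0.40 (SE), 1.95 and 2.78 within the array numbers, limma adjusted p = 0.403 over all 9335 probe sets), and this independent probe set argues against noise of the dim URA3 gene probe set. A rise of the pathway together with URA3 is argued against by URA1 and URA4, with log2 changes of −1.31 and −0.71. URA10 went the other way (0.58) but lay under background, at 16.55 and 24.7. The median of URA1, URA4 and URA10, on which the test was set, was −0.71 (−0.90 and −0.52 within the numbers). SEY6210 carries a ura3 mutation, so a URA3 marker brought in when the mutant was built is a candidate explanation that was not tested, since how the strain was made is not given in the sources used here. An effect of the pmt1 pmt2 mutations on URA3 also stays open, as untested.

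Probe sets that name no gene or several genes were left out of the gene comparison, and some of them differed. Of 2443 probe sets without a gene name, 963 had a higher group mean above background, and 43 of these were at least 2-fold apart in the same direction within both array numbers, 18 higher and 25 lower in pmt1 pmt2, with 0 past limma's test over all probe sets and 34 at unadjusted p under 0.05. Of 328 probe sets that name several genes, 272 were above background, and 13 of these were so, 2 higher and 11 lower, with 0 past limma's test and 9 at unadjusted p under 0.05.

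YAR068W was at least 8.36-fold lower in pmt1 pmt2, and a probe set that names it together with other genes measured 140 ± 35.3 and 13.25 ± 8.41 (at least 5.26-fold lower). Loss or silence of the segment of chromosome I around it may be the cause and stays open: of its measured neighbours only SWH1 was above background, with a log2 change of −0.19 (−0.49 and 0.10 within the numbers), which is too few to decide. Signal shared with the near-identical copy YHR214W-A cannot be told apart from signal of YAR068W, since 0 probe sets name that copy. A probe set that names the neighbouring genes of both copies, YAR066W and YHR214W, measured 56.95 ± 33.2 and 13.55 ± 10.5 (at least 1.98-fold lower). An effect of the pmt1 pmt2 mutations on this gene was not tested against these explanations.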

How the results depend on the processing

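The replicate block with a minimum mean of 6, and the block with a mean-variance trend, were chosen after seeing the data, and the others were planned. The number of genes changed at adjusted p under 0.05 was 22 (16 genes higher in pmt1 pmt2, 6 genes lower in pmt1 pmt2) and depended on the processing. The cause was not tested except where stated. Quantile normalization gave 2 (0 higher, 2 lower), centring gave 14 (9 and 5), and raising low values to 4 gave 1 (0 and 1). With a minimum mean log2 value of 6, and so fewer genes tested, 38 changed (28 and 10), and over every probe set, with more tests, 0 did (0 and 0). The replicate block gave 171 (131 and 40), the block with that minimum gave 601 (369 and 232), and the block with the trend gave 729 (458 and 271). By deposited values, under background or not, the number of genes changed at least 2-fold at adjusted p under 0.05 was 2 by quantile normalization, 14 by centring, 1 with low values raised, 38 with the minimum, 0 over every probe set, 171 with the block, 272 with block and minimum, and 415 with block and trend. A minimum of 4 gave 27, the trend 23, robust spread 23 and the mean of probe sets 22. Leaving out 1 array assumes that the lone array of a group varies like the other group, and gave 0 to 62 genes (0 to 45 higher, 0 to 17 lower, 0 to 62 by at least 2-fold). The labels do not pair the arrays, and the pairing correlation behind the replicate block was 0.65 over all genes and 0.83 over genes with a mean of at least 6. The PMT1 log2 fold change kept its sign but not its call after quantile normalization (−3.24, limma adjusted p = 0.0753), centring (−3.27, 0.0593), raising low values (−3.18, 0.285) and over every probe set (−3.18, 0.307). It ran from −3.45 to −2.91 with 1 array left out, and its adjusted p over all settings from 1.01e-34 to 0.307. The PMT2 log2 fold change lost its call over every probe set (−7.64, limma adjusted p = 0.120) and ran from −7.83 to −7.45 with 1 array left out, with adjusted p over all settings from 3.18e-180 to 0.120. The cell wall integrity targets list (median 1.47) and the unfolded protein response targets list (0.65) stayed past camera except with an estimated correlation (adjusted p = 0.649 for both) or by fry (0.195 and 0.244). Leaving out pmt1 pmt2 array 1 or array 2 moved the median of all genes from 0.027 to 0.24 or −0.14. These fits had no block and left the groups unequal in array number, so list medians without 1 array include this shift. Some list medians changed sign, not only those near 0. With 1 array left out the medians ran from −0.093 to 0.56 in the ER-associated degradation list, −0.0029 to 0.20 in the N-glycosylation list, −0.42 to 0.089 in the a-cell genes list, −0.19 to 0.15 in the heat shock chaperones list, −0.075 to 0.82 in the sulfur and methionine list, and −0.47 to 0.22 in the iron regulon list. They ran from −0.11 to 0.086 in the glycolysis and fermentation list, −0.24 to 0.037 in the hexose transport list, −0.33 to 0.15 in the ergosterol synthesis list, −0.23 to 0.14 in the phospholipid synthesis list, −0.49 to 0.24 in the daughter cell separation list, −0.54 to 0.37 in the histones list and −0.088 to 0.79 in the strain marker loci list. The STE3 log2 fold change ran from −0.63 to 0.011. Quantile normalization turned the median of N-glycosylation (−0.011), glycolysis (0.023) and daughter cell separation (−0.024), and centring that of N-glycosylation (−0.066) and daughter cell separation (−0.080). Signal over background limits what can be said of 602 genes at or below 26.2 on all arrays.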

Other observations

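The tests that set the pheromone response genes against technical explanations were chosen only after the result was seen, as were the genes named here except MFA2, while quantile normalization and centring were planned.

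Several genes outside the lists differed in the same direction in both array numbers, and passed limma's test with the replicate block, whose adjusted p is given here. SNZ1 (YMR096W) and SNO1 (YMR095C), a divergent pair for vitamin B6 synthesis, measured 29.0 ± 7.07 and 22.6 ± 8.84 in wild type and 170.1 ± 48.01 and 118 ± 35.3 in pmt1 pmt2 (limma adjusted p = 0.00437 and 0.0211). The wild type mean of SNO1 lay under background, so its rise was at least 4.42-fold. ANB1 (YJR047C), the translation factor made when oxygen is low, measured 763 ± 244 in wild type and 142 ± 37.7 in pmt1 pmt2 (limma adjusted p = 0.00542). The ATP/ADP carrier gene AAC3 (YBR085W) measured 74.5 ± 42.1 and 20.3 ± 5.66 (at least 2.61-fold lower, limma adjusted p = 0.0236). PCK1 (YKR097W), of gluconeogenesis, measured 53.1 ± 23.1 and 346 ± 229 (limma adjusted p = 0.00542). SPS19 (YNL202W) and TES1 (YJR019C), of fatty acid oxidation in peroxisomes, measured 139 ± 11.5 and 110.1 ± 16.1 in wild type and 426 ± 135 and 323 ± 137 in pmt1 pmt2 (limma adjusted p = 0.0325 and 0.0439), and ADR1 (YDR216W), the activator of such genes, 34.5 ± 13.5 and 102 ± 41.5 (limma adjusted p = 0.02698). None of these 8 genes passed limma's test without the block, where their adjusted p ran from 0.0998 (SNZ1) to 0.467 (ADR1).

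LEU1 (YGL009C), for isopropylmalate isomerase, measured 960.5 ± 312 in wild type and 295 ± 141 in pmt1 pmt2 (limma adjusted p = 0.396, 0.0205 with the block), and BAT1 (YHR208W), a branched-chain aminotransferase, 2235.5 ± 460.3 and 1003 ± 37.5 (limma adjusted p = 0.499, 0.0814 with the block). The retrotransposon Ty3, whose transcription is known to be induced by pheromone, was represented by YGR109W-B at 3631 ± 1169 and 1284 ± 148 (limma adjusted p = 0.364, 0.0401 with the block). Of 23 probe sets that name this element alone, 19 were lower in pmt1 pmt2 within both numbers, with a median log2 change of −0.91.

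The lower pheromone response genes (median log2 change −0.83) were set against technical explanations. Each group holds 1 array of each number, so a difference between the numbers cancels in the comparison, and the medians within them, −1.08 and −0.62, were both below those of all genes, −0.15 and 0.21. After quantile normalization and centring the list medians were −0.87 and −0.92, against −0.035 and −0.066 for all genes. Centring moves all genes of an array alike, so its outcome followed from the array medians and was no test of scaling. Quantile normalization can move genes by signal level and left the list lower, which argues against scaling of that kind. Cells of the a mating type among the wild type cultures, whose pheromone would act on the alpha cells of SEY6210, may account for the pattern and stay open. MFA2 was lower, whereas MFA1, the other pheromone gene of a cells, measured 31.7 ± 10.04 and 37.05 ± 9.55, near background. Leaving out MFA2, and also AXL1, which haploid cells of either type make, the a-cell genes had a median log2 change of −0.070. Of these genes 0 were above background on both wild type arrays, which is too few to decide. Cultures free of a cells would also leave these genes under background, so the test as set could not have argued against a cells. An effect of the pmt1 pmt2 mutations on this pathway also stays open, as untested.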
